A study of Rattus norvegicus with 4 samples.

How the data were processed

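MicroRNA levels were measured on single-colour oligonucleotide arrays in male rats of 2 strains, with 2 arrays from Goto-Kakizaki (GK) rats and 2 from Wistar rats. Total RNA was labelled by PCR with a Cy5 primer, per the labels' protocols. The labels name no tissue or organ, so none is given here. Per the series' design text, each sample had independent small RNA libraries (biological replication) and repeat hybridizations of each library (technical replication). The labels do not say which of these the 2 replicate numbers of a strain stand for. The p-values therefore measure only the spread between these arrays, which may be technical.

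Each scanner table held 1296 spots in 4 blocks of 18 rows and 18 columns, for 432 probe codes printed in 3 spots each. The intensity values were deposited as linear pixel intensities per spot at 635 nm, with foreground mean and median, local background mean and SD, and no normalization between arrays. The scanner software and its settings are not given in the sources used here. The deposited signal-to-noise score was, per the file headers and a check of the values, the foreground mean minus the background mean, over the background SD. The deposited percent of saturated pixels per spot was also used. No spot carried a flag, and the local background median was 0 at every spot, so foreground and background means were used. The authors' value table held the foreground median intensity, unlogged, uncentred and unscaled: 0 of its cells differed from the scanner tables. Its medians per array were 0, 0, 0 and 100 for GK replicates 1 and 2 and Wistar replicates 1 and 2.

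The codes fell into 406 beginning with M, 14 with N, 8 with P and 4 with B. The files do not define these letters and do not pair any code with a microRNA name or sequence. The M codes, by far the largest class, were taken as the microRNA probes, and the others were described apart. The microRNA lists fixed before the data were examined (striated muscle, glucose and insulin, let-7, blood cell, liver and other tissue lists) could not be matched to codes, so their set tests and a test of rat probes alone were not run. The rule fixed for naming probes took those past the threshold whose groups did not overlap, by the size of the difference. Because codes carry no identity, only the first 2 in each direction are named, ordered by the fitted difference, which for a code not detected in GK, such as M38, is no bound; M92, which had the largest bound, was added after the values were seen. The parts of the rule that draw on lists and on the brightest probes were not used.

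Foreground intensities were corrected with normexp (offset 50) on the local background mean, log2 transformed and quantile normalized between arrays, and the 3 spots of a code were averaged (limma 3.58.1 in R 4.3.3). The N, P and B codes entered this normalization with the M codes, whereas the plan left control spots out after normexp. A code was detected on an array when at least 0.5 of its spots exceeded the background by 2 background SDs. The 122 M codes detected on both arrays of at least 1 strain were tested with lmFit and eBayes on all 4 arrays with strain as the only term, two-sided, with Benjamini-Hochberg adjustment over the 122 codes and a threshold of 0.05. This leaves 2 residual degrees of freedom, to which the moderation added 2.00. For a code detected on no array of a strain, the difference is also given as a bound: the mean of the brighter strain against, per dim array, the higher of the lowest signal among detected M codes and the code's own signal. A code was saturated on an array when at least 0.5 of its spots had a median at 65535, the top of the scale. Fold changes are on the normalized log2 scale after the offset of 50, which understates changes of dim codes. The number of arrays limits the precision.

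The procedure was tested on simulated data, in 50 simulations each with 122 tested codes of which 30 were changed by 1 and 30 by 2 on the log2 scale. Every simulated code was given the same spread between arrays, the median SD of the tested codes, whereas the spread of real codes varies. The simulated loss of signal on the GK arrays was smaller than the median unscaled difference of the tested codes, -1.78. The set of tested codes was also kept fixed. The rates below therefore need not hold for the data. With equal numbers raised and lowered, 69.2% of the smaller and 98.7% of the larger changes were recovered, and 6.10% of calls were false. With all 60 changed codes lowered, 24.9% of the smaller and 98.3% of the larger changes were recovered, and 27.6% of calls were false. On average 14.7 of the 62 unchanged codes were then called higher, because quantile normalization assumes alike distributions.

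Alternatives varied the background correction, the scaling between arrays, the filter on dim codes, the source of the values, the spot average, the variance model, a block for the replicate number, and each array left out in turn. Some settings were chosen after seeing the data. These were scaling to the P codes, a block for the position of the spot grid, a test without codes holding any saturated pixels and a test that included the N, P and B codes. Same-numbered arrays of the 2 strains were checked for pairing: their deviations from the strain means correlated at r = 0.02 over the 122 codes and r = 0.14 over all 406 M codes. There are only 2 pairs, and the labels tie the numbers to no shared animal or day, so the arrays were treated as unpaired.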

Results

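MicroRNA signal was compared between male GK rats, an inbred model of type 2 diabetes derived from Wistar rats with poor glucose tolerance, and normal male Wistar rats. The animals were kept on standard chow over 14 weeks. The comparison asked which microRNAs differ in level between the diabetic and the normal strain. Each strain was represented by 2 single-colour arrays carrying 406 probe codes of the M series, which are taken as the microRNA probes. The codes are not paired with microRNA names in the files, so probes are described by code, by class and by signal.

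The GK arrays showed fewer probes above background than the Wistar arrays. Of the 406 M codes, 17.7% and 16.5% were detected on GK replicates 1 and 2, against 30.8% and 39.7% on Wistar replicates 1 and 2. All 4 arrays detected 57 codes and no array detected 237. Both Wistar arrays and neither GK array detected 47 codes, and 0 codes showed the opposite. The median foreground intensity over the 1296 spots was 88.0 and 222 on the GK arrays and 297 and 470 on the Wistar arrays, and the median local background was 39.0, 96.0, 83.0 and 86.0. The tested codes had a median signal-to-noise score of 2.62 and 2.29 on the GK arrays and of 6.997 and 10.9 on the Wistar arrays. This score also chose the tested codes, and more of them entered through the Wistar arrays alone than through the GK arrays alone. Part of the gap may follow from that choice. The 3 spots of a code scattered by an SD of 0.24 to 0.32 on the log2 scale within an array.

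Among the 122 tested M codes, arrays of one strain were closer to each other than to arrays of the other strain. After quantile normalization the GK arrays correlated at r = 0.95 across codes and the Wistar arrays at r = 0.97, whereas the 4 pairs of arrays from different strains ranged from r = 0.75 to 0.82. Over all 406 M codes before scaling, GK replicate 1 was no closer to GK replicate 2 (Spearman's rho = 0.76 across codes) than to Wistar replicate 1 (rho = 0.76), and the Wistar arrays correlated at rho = 0.81. Codes are not independent replicates, and these values describe the 4 arrays only. The median absolute difference per code was 0.38 between the GK arrays, 0.22 between the Wistar arrays and 0.94 to 1.01 between arrays of different strains.

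Of the 122 M codes tested, 59 passed the threshold between strains: 26 were higher and 33 were lower in GK rats (limma, Benjamini-Hochberg adjustment). The remaining 63 did not pass, and 63 codes had an unadjusted p under 0.05. The higher codes rose by 0.69 to 2.62 on the log2 scale, with a median of 1.40, and 1 of them, the one with the smallest rise, was saturated on 1 GK array. With codes holding any saturated pixels on any array left out, 50 of 106 codes passed, 21 higher and 29 lower. Of the 35 called codes detected on a GK array, 27 differed by 2-fold or more, and of the 24 detected on no GK array, 7 had a bound of 2-fold or more. Over the 57 codes detected on all 4 arrays the values of the 2 strains did not overlap for 42, or 73.7%, and over all 406 M codes for 225, or 55.4%, where chance gives 33.3%. All codes share the same 4 arrays, so a share above this is no test of strain differences. The split into higher and lower codes depended on the filter. The 47 codes detected on both Wistar arrays and no GK array held 24 lower calls and 0 higher calls. There were 0 codes with the opposite pattern of detection. With only the 57 codes detected on all 4 arrays tested, 22 were higher and 8 lower. The split also depended on the scaling between arrays. It was 1 higher and 79 lower without scaling, 8 and 66 with the median of all M codes, 29 and 29 with the 75th percentile of codes detected everywhere, 27 and 28 with cyclic loess, and 36 and 12 with the mean of the P codes. The median difference over the tested codes was -0.34 after quantile normalization, -1.78 without scaling and 0.32 with the P codes. After quantile normalization its sign also turned with the set of codes: it was 0.04 over all 406 M codes and 0.13 over the 57 detected on all 4 arrays. Without Wistar replicate 1 the calls were 34, of which 13 were higher and 21 lower. The higher calls were 15 without GK replicate 2 and 16 without Wistar replicate 2.

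**Figure D1:**
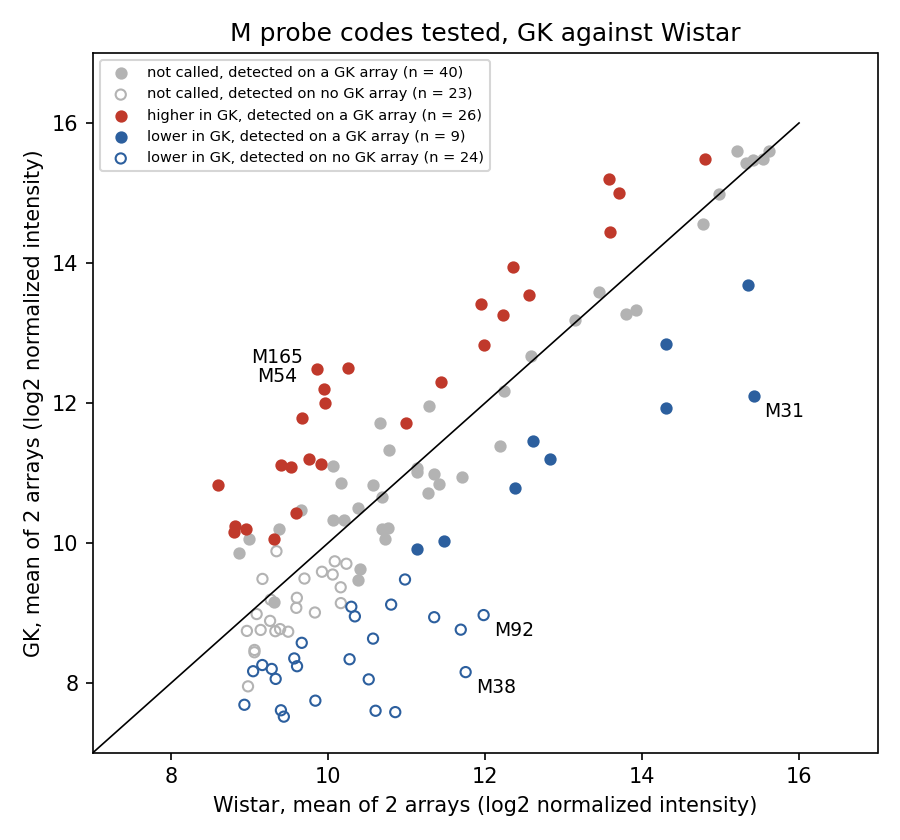
Mean log2 normalized intensity of the 122 tested M codes in GK rats (vertical axis) against Wistar rats (horizontal axis), each the mean of 2 arrays, with the line of equality. Filled points were detected on at least 1 GK array, open points on none; the 26 higher codes are all filled, and 24 of the 33 lower codes are open.

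The codes called higher were mostly detected in both strains. The filter admitted 0 codes detected on both GK arrays and no Wistar array, so this was partly set in advance. Of the 26 higher codes, 21 belonged to the 57 codes detected on all 4 arrays, 4 to the 4 codes detected on both GK arrays and 1 Wistar array, and 1 to the 14 codes detected on both Wistar arrays and 1 GK array. M165 had the largest rise, with a normalized log2 signal of 12.48 ± 0.54 (SD, n = 2) in GK rats and 9.86 ± 0.60 (SD, n = 2) in Wistar rats. Its log2 difference was 2.62 (SE 0.44), or 6.16-fold, with an adjusted p of 0.014 by limma. M54 was next, at 12.20 ± 0.58 (SD, n = 2) in GK rats against 9.94 ± 0.11 (SD, n = 2) in Wistar rats. Its log2 difference was 2.26 (SE 0.34), or 4.78-fold, with an adjusted p of 0.012 by limma. M165 was higher under all 6 scalings with a call under each, and M54 stayed higher under all of them but was not called without scaling (0.84, adjusted p = 0.095 by limma).

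Most codes called lower did not clear the background in GK rats, which follows partly from the filter. It admitted 47 codes detected on both Wistar arrays and no GK array, and 0 codes of the opposite kind. Lower calls were therefore favoured in advance in this class. Of the 33 lower codes, 24 were not well above background on either GK array, so their difference is only bounded. For 14 of these the bound was at least 1.04-fold to at least 4.61-fold lower in GK, the last for M92, singled out after its values were seen. The adjusted p of 0.0078 by limma for M92 belongs to its fitted difference, which uses GK signal near background, and not to the bound. For the others the bound was below 1-fold, the lowest at 0.56-fold. It shows no fall for them, although limma called these codes lower. These bounds are after quantile normalization; that of M92 was at least 2.83-fold with the P codes as the scale and at least 12.2-fold without scaling. The other 9 lower codes were detected on at least 1 GK array, 7 of them on all 4 arrays. Of these 9, 2 were saturated on a Wistar array, and the 7 others had log2 differences of -1.16 to -2.38. Among these 7, M73, at -2.38, and M30 held some saturated pixels, so their falls may be understated. M31 fell from 15.42 ± 0.35 (SD, n = 2) in Wistar rats to 12.09 ± 0.30 (SD, n = 2) in GK rats. Its log2 difference was -3.33 (SE 0.29), with an adjusted p of 0.0078 by limma. Its spots were saturated on 1 of the 2 Wistar arrays, replicate 2, so the fall may be understated. The difference was -3.29 without that array, -2.46 with the 75th percentile and -1.86 with the P codes. M38 was detected on both Wistar arrays at 11.75 ± 0.05 (SD, n = 2) and on neither GK array, where its measured mean was 8.15 ± 1.005 (SD, n = 2). It was at least 3.93-fold lower in GK after quantile normalization and at least 2.51-fold lower with the P codes as the scale. The adjusted p of 0.012 by limma belongs to its fitted difference of -3.60, which uses GK signal near background, and not to the bound. Both M31 and M38 were called lower under all 6 scalings.

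Divided by mean signal, the 41 brightest tested codes held 14 higher and 7 lower calls, the middle 40 codes 9 and 9, and the 41 dimmest 3 and 17. The median unscaled log2 difference in these groups was -0.61, -1.87 and -1.99, and whether the groups differ was not tested. Codes that entered the test through the Wistar arrays alone favour lower calls and were not set apart here. Across the 6 scalings no code was called higher under one and lower under another (0 codes). Of the 26 higher codes 12 had a positive difference under every scaling, and of the 33 lower codes 30 had a negative one, the other 3 being positive with the P codes. 12 codes were called lower under every scaling, 2 of them detected on both GK arrays, and 1 code, M165, was called higher under every scaling. Of the 26 higher codes, 25 were also called higher with the P codes as the scale and 1 without scaling. Of the 33 lower codes, 12 were also called lower with the P codes and all 33 without scaling.

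**Figure D2:**
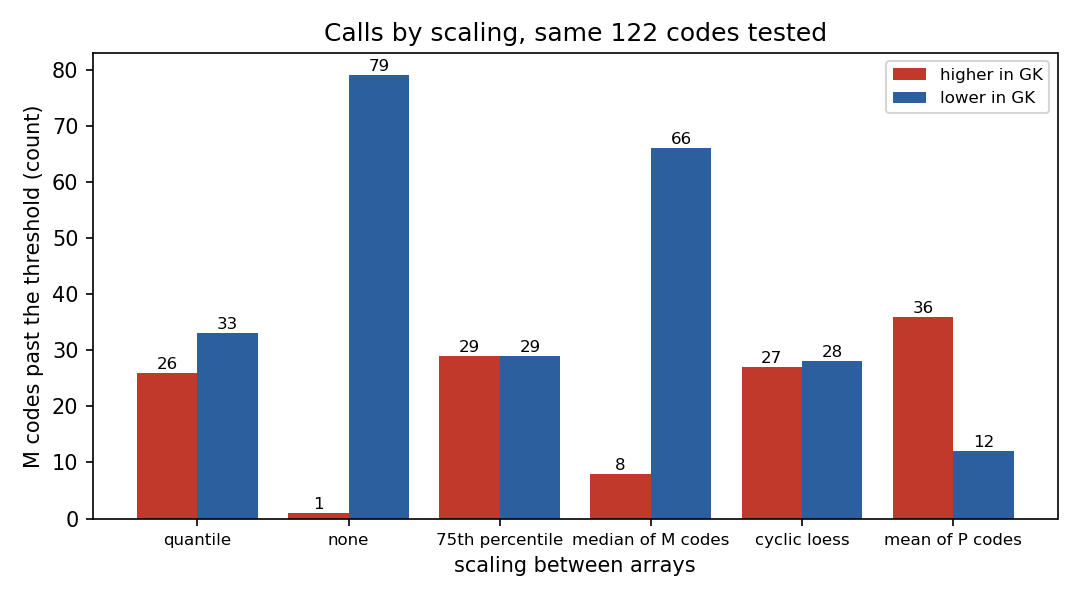
Number of the 122 tested M codes called higher (red) and lower (blue) in GK rats under each scaling between arrays, at an adjusted p under 0.05. Higher calls ranged from 1 without scaling to 36 with the P codes, and lower calls from 12 to 79.

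Outside the M series, signal above background was found mainly among the P codes, whose signal tended to climb with the number in the code. All 8 were detected on both Wistar arrays, and of these 4 were detected on both GK arrays, 2 on 1 GK array and 2 on none. The unscaled log2 mean of the 4 codes detected on every array was 9.88 ± 0.00035 (SD, n = 2) on the GK arrays and 12.32 ± 0.21 (SD, n = 2) on the Wistar arrays, a median of 5.38-fold lower. An exact two-sided permutation test gave p = 0.33, the smallest p that 2 arrays against 2 allow. Their unscaled differences ranged from -2.37 to -2.54. The small SD on the GK arrays comes from averaging codes that moved in opposite directions. P20S was at 10.15 and 9.86 on GK replicates 1 and 2, and P25S at 10.06 and 10.20. Of the 2 codes not well above background on either GK array, P5E was at least 1.55-fold and P10E at least 1.99-fold lower before scaling. The 4 B codes were detected on no array. Of the 14 N codes, 2 were detected on each GK array and 2 and 5 on Wistar replicates 1 and 2.

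**Figure D3:**
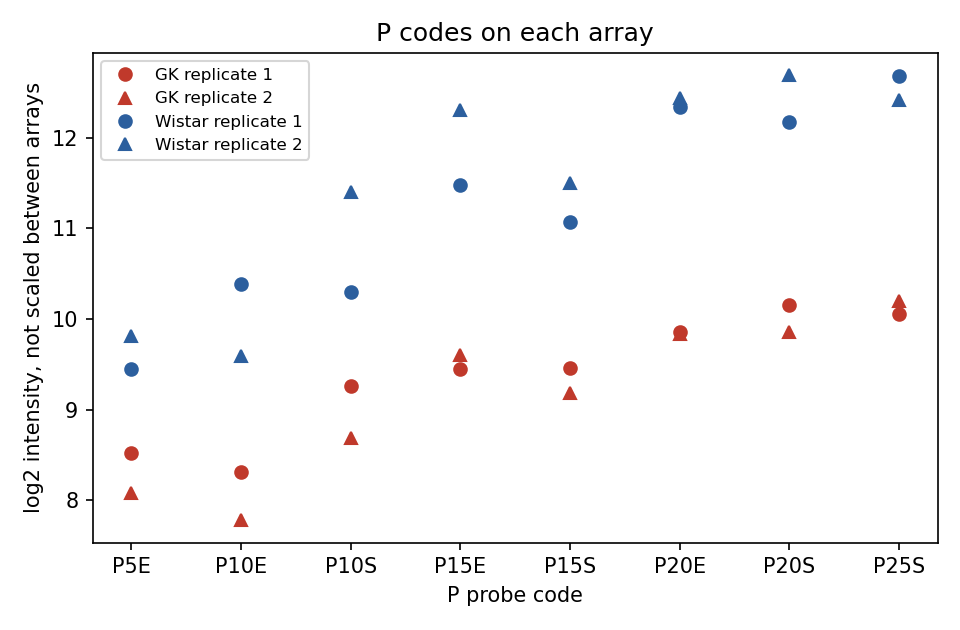
Log2 intensity of each of the 8 P codes on each array after background correction and before scaling between arrays (red, GK; blue, Wistar; each point is the mean of 3 spots). The measured signal of every P code lies lower on both GK arrays than on both Wistar arrays, and P5E and P10E were not well above background on either GK array.

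The arrays also differed in the position at which the spot grid began, which crossed the strains: GK replicate 1 and Wistar replicate 2 shared a low start, and GK replicate 2 and Wistar replicate 1 a high start. With this position as a block, 64 codes passed, 27 higher and 37 lower (limma). Within each position there was 1 array per strain and no test. M165 differed by 2.58 and 2.66 on the log2 scale in the low and the high position, and M54 by 1.93 and 2.59.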

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

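All tests in this part were chosen after the results were seen. Some N codes, which the main comparison leaves out, carried signal on both GK arrays above that on both Wistar arrays after quantile normalization. N4 was higher in GK by 2.40 on the log2 scale, at 11.16 and 11.56 on the GK arrays against 8.84 and 9.08 on the Wistar arrays, and by 1.02 before scaling. N3 was higher by 1.27, at 11.23 and 11.70 against 10.06 and 10.33, but lower before scaling (-0.30). With the N, P and B codes tested too, the adjusted p was 0.0070 for N4 and 0.022 for N3 (limma). Both were detected on all 4 arrays, and what N codes bind is not stated in the files.

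Before scaling, the signal of most tested probes was lower on the GK arrays. A single array-wide factor as the whole cause is argued against by the scatter: over the 41 M codes detected everywhere without saturated pixels, the unscaled differences had an SD across codes of 1.04, against 0.41 from replicate arrays, and 7 of the 41 were above 0. A loss shared with the P codes as part of the cause stays open. The 4 P codes detected on every array were lowered more than those M codes (difference of medians -1.56, SD over these P codes 0.07), which is possible if P codes report labelling or hybridization yield and many microRNAs rose, or if P codes respond to something else, since their identity is not given. In simulations where all changed codes were lowered, quantile normalization called 14.7 of 62 unchanged codes higher on average, so part of the 26 higher calls may come from scaling. A lower microRNA content in GK rats is the biological explanation the design allows, and it was not tested.

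The median unscaled difference was near 0 among M codes with a mean unscaled log2 signal over 12. Still, 9 of these 26 codes were lower by more than 1 on the log2 scale before scaling, the lowest at -3.96. Detector saturation may contribute, since saturated pixels cannot rise further, but the test left it open: the 16 with saturated pixels differed by a median of -0.10 and the 10 without by -0.26, a gap of 0.15 against an SD of 0.62 among the latter. The 16 codes with saturated pixels ranged from -3.96 to 0.94. Strain differences in those microRNAs were not tested as an explanation.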

How the results depend on the processing

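Scaling to the P codes, the grid position block, and the tests without codes holding saturated pixels or with N, P and B codes were chosen after seeing the data. The total of 59 calls stayed within 1.5 times under all settings but 2: it was 30 when only codes detected on all 4 arrays were tested, a filter that removes codes lost in GK, and 34 to 66 over the settings that left out 1 array, the lowest without Wistar replicate 1. Leaving out 1 array gave 13 to 26 higher calls, 21 to 40 lower calls and 44 to 71 codes at an unadjusted p under 0.05, with the lone array of a strain taken to vary like the other strain's. The 26 higher calls became 1 without scaling, 8 with the median of all M codes, 16 of 406 codes without a filter, and 17 with the replicate number as a block. The 33 lower calls became 79 without scaling, 66 with the median of all M codes, 12 with the P codes and 8 among codes detected on all arrays. Codes at an unadjusted p under 0.05 numbered 63, against 105 without a filter and 31 among codes detected on all arrays. The replicate block gave 45 calls in all (17 higher, 28 lower). Deviations of same-numbered arrays correlated at r = 0.02 over the tested codes and r = 0.14 over all M codes; with 2 pairs and no label that ties the numbers, the arrays were not treated as paired. Background settings, the authors' values (63 calls, 25 higher), the spot median and robust variances kept each of these counts within 1.5 times, and causes were not tested beyond what each setting's construction shows. No named code reversed. M165 ranged from 1.27 to 3.75 over 20 alternatives and was called under each, and M54 from 0.84 to 3.23 with 1 call lost. M31 ranged from -1.86 to -3.96, M38 from -2.61 to -6.09 and M92 from -2.19 to -5.48 (fitted values). These last 3 were called under all 19 alternatives that tested them. The smallest falls of these 3 came with the P codes. Detection on Wistar replicate 2 was 242 codes at background plus 1 SD against 161. Sets of rat probes alone, kept flagged spots and set tests of microRNA lists were not run, since codes carry no names and no spot was flagged. Signal over background limits the lower calls, 24 of which were not measured in GK.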

Other observations

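The split of codes and the gradient test were chosen after the results were seen; the matching on signal level was written before its result, and its bootstraps were added after. The position of a code in the numbering went with its direction, a split noticed in the data at the place where the N codes interrupt the M codes. Of the 21 tested codes above M317, 9 were higher and 1 was lower in GK, with a median difference of 0.67. Of the 101 tested codes up to M317, 17 were higher and 32 lower, with a median of -0.39. No p is given for the difference of 1.06, since the split was chosen from the same values and codes are not replicates. Before scaling the medians were -0.60 and -1.90. The 32 lower codes up to M317 include all 24 lower codes detected on no GK array, which entered the test through the Wistar arrays alone. The 2 ranges were not matched on detection, so its part in the split was not tested and stays open.

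Because the later codes lie in rows 14 to 18 of each block, a signal gradient along the array was weighed first. Among the 4 P codes detected on every array, the mean difference of the 2 in the last row minus that of the 2 in the first row was -0.029 (SE 0.085) before scaling, where a gradient needs about 1.30. Both pairs lie in blocks 1 and 2, so blocks 3 and 4 were not covered. The difference between rows argues against a gradient in the 2 covered blocks if these P codes would otherwise respond alike, which is not stated. Signal level as the whole cause is argued against by matching: within 3 bands of mean signal the mean difference was 0.84 (bootstrap SE 0.29), against 0.92 unmatched. That lies above 0.5 times the unmatched value by 0.38 (bootstrap SE of this excess 0.18), a narrow margin. Codes are not replicates, so this describes these codes only, and signal level as a part of the cause stays open. The permutation planned beside it was dropped because the split came from the same data. Another candidate explanation, as a hypothesis, is that the later codes are a different set of microRNAs that differs between strains; no biological explanation was tested, since codes carry no names.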
